A study of Bos taurus with 8 samples.

How the data were processed

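Small RNA was sequenced from cultured alveolar macrophages of 8 cattle, 1 library per animal. Per the labels' protocols, thawed lavage cells were kept for 24 hours at 37 °C and 5% CO2 in medium with 10% fetal bovine serum. Non-adherent cells were removed. The small RNA fraction was prepared from the detached adherent cells, and 8 µL of it entered a multiplexed small RNA library kit. Any small RNA carried over from this serum, which is of the same species, could not be told apart from that of the cells. The submitters' processing notes name CASAVA 1.8.2, FastQC 0.10.0, cutadapt 1.0 (an adapter trimmer), Novoalign 2.07.11 (a short read aligner) and HTSeq (a read counter with no version stated), without giving their roles, settings or order. The genome build, the annotation release, the treatment of reads that match several loci and the use of strand are not given in the sources used here. Genes with near-identical copies are therefore uncertain, because their reads could have been dropped or divided. The table has 1 row per gene, so the 2 arms of a precursor and their length variants are not separated in these values.

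The deposited table holds CPM values, the reads of a gene per 1000000 assigned reads, since each column sums to 1000000 over the genes of the table; the unit was read from the values. Within each column the values are whole multiples of the smallest, so the authors' counts could be recovered: 100% of the 2379 values above 0 came out as whole reads within 0.02 of a read. The recovered totals run from 3638161 to 5888148 per library, and 1 read is worth 0.170 to 0.275 CPM. At a mean of about 100 CPM, counting error amounts to a coefficient of variation of at most 4.42%. Low genes are correspondingly less precise, and intervals and limits cover counting error only. All columns of the table were used and each was matched to its animal by its title.

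The rows are Ensembl gene identifiers. None of the 1153 (0 matched) could be paired with a symbol, so no gene is named. The gene table used here, of the reference assembly ARS-UCD2.0, held no Ensembl identifiers to match. Several kinds of planned comparison that need names were left out for this reason: the arms of a precursor, related microRNAs, lists of cell-type and pathway microRNAs, members of genomic clusters, and correlations between lists. Only 4 identifiers are printed, and other genes go by their rank in mean abundance.

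The libraries form 1 group of separate animals. Means and SDs were taken over animals. Log values are log2(CPM + 1), a scale that understates changes of low genes. Genes with a mean of at least 10 CPM count as detected, and the spread between animals was measured on genes with a mean of at least 100. Before the data were examined it was fixed that the 20 most abundant genes and, among genes with a mean of at least 100, the 8 with the largest and the 5 with the smallest SD of log2 values would be described. Neighbouring ranks among the 20 most abundant genes were compared within animals by a two-sided exact sign-flip permutation test with Benjamini-Hochberg adjustment; this test and the test against counting error were chosen after the data were examined. The latter set each gene's dispersion index against 10000 random assignments of its recovered reads to the libraries. With edgeR 4.0.16 in R 4.3.3, the common biological coefficient of variation of the genes with a mean of at least 10 CPM was 0.43. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. An animal was called an outlier in a measure where Dixon's ratio exceeded the 95% critical value for 8 samples.

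The test against counting error was tested on simulated data for the real genes and library sizes, with 389 genes entering the step. Of the 194 simulated genes without a change 1.55% were called. Of genes raised in 2 of the libraries, it called 20.4% at 1.25-fold, 42.6% at 1.5-fold, 57.1% at 2-fold and 62.0% at 4-fold, and all changed genes it missed had under 500 reads on average. Among genes with at least 500 reads on average it called all 37 changed ones. The sign-flip test gave a p under 0.05 in 3.95% of 2000 simulations without a difference. In these simulations nothing was ordered by level, so the rate does not cover pairs ranked on the tested values. Alternatives tried were other scalings (median-of-ratios, TMM, and CPM without the 2 most abundant genes), pseudocounts of 0.5 and 10, lower and higher minimum levels, thinning of every library to the shallowest, and leaving out each animal in turn.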

Results

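The study profiled small RNA of alveolar macrophages, the resident phagocytes of the lung air spaces, from 8 cattle. The cells had been washed out of the lungs, stored frozen, thawed, and cultured for 24 hours, after which the adherent cells were lysed. Each animal gave 1 library, and the 8 libraries form a single group, so no treated or control group enters any comparison. The libraries held between 3638161 and 5888148 reads assigned to genes, 40056324 in all. Levels are given in CPM, reads per 1000000 assigned reads of a library. The table lists 1153 bovine Ensembl gene identifiers, which the file does not pair with microRNA names. Genes are therefore identified below by their rank in mean abundance, with the identifier of 4 of them. Where these genes lie in the genome and which microRNA each encodes is not reported here.

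The first question was which genes make up the small RNA profile of these cells. A single gene, ENSBTAG00000029897, took 79.3% ± 1.77 (SD, n = 8) of all assigned reads. Its share was lowest in animal 4, at 75.9% (exact Clopper-Pearson 95% interval 75.89 to 75.96%), and highest in animal 8, at 81.4% (81.38 to 81.45%). The next gene, ENSBTAG00000029996, took 7.44% ± 1.88 (SD, n = 8), with values from 4.89% in animal 8 (4.87 to 4.91%) to 10.4% in animal 1 (10.42 to 10.47%). At rank 3, the share was 1.75% ± 0.157 (SD, n = 8). Together the first 10 genes held 92.8% ± 0.852 (SD, n = 8) of the reads and the first 20 held 95.9% ± 0.395. These intervals cover counting error only, since no molecular identifiers are described for these reads. Shares, ranks and ratios between genes are those of reads. Whether library preparation turned each RNA into reads at the same rate was not tested.

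**Figure D1:**
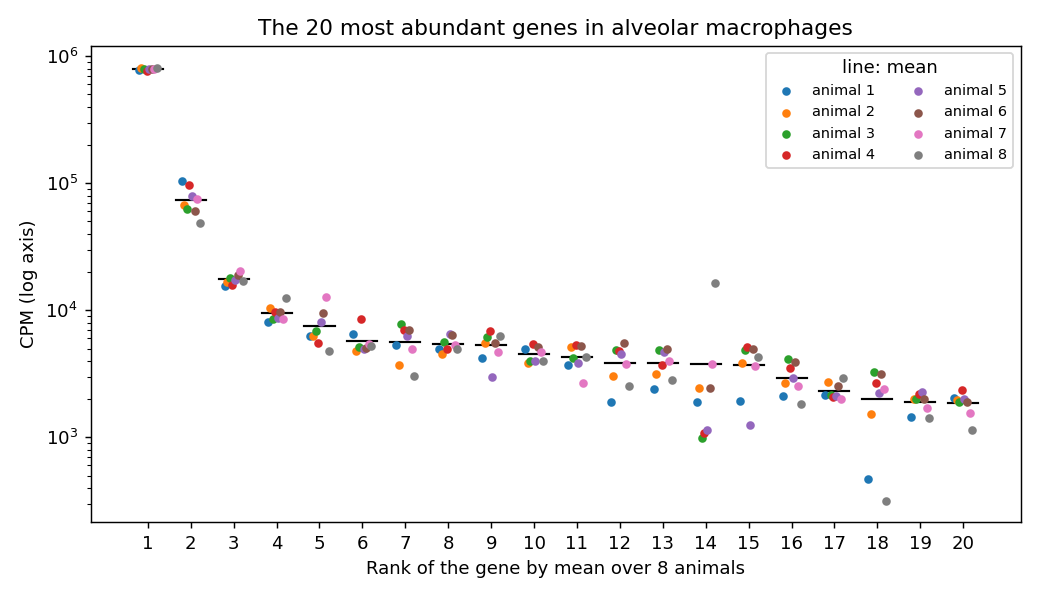
CPM (log axis) of the 20 most abundant genes, ordered by their mean over 8 animals. Each point is 1 animal and each line the mean. The gene at rank 1 lies near 792527 CPM in all 8 animals, and the gene at rank 14 has 1 high point, animal 8 at 16287.

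Below these leading genes the profile fell away steeply. Averaged over the animals, 3 genes lay at or above 10000 CPM and held 88.4% of the reads. A further 34 genes lay between 1000 and 10000 CPM and held 9.65% ± 0.924 (SD, n = 8). The next 43 genes, between 100 and 1000, held 1.65% ± 0.199. Another 63 genes, between 10 and 100, held 0.23% ± 0.032. The remaining 259 genes with any read held 0.034% of the reads. Of all these genes, 50 sufficed to hold 99% of all reads. Reads were found in all 8 animals for 225 genes and in 1 animal for 63 genes. The other 751 genes of the table had no read in any library. With 3 reads taken as the limit that a count of 0 allows, their level lies under 0.509 CPM in the deepest library and under 0.825 in the shallowest. This limit holds only for genes whose reads were not set aside in counting. How reads that match several loci were treated is not given in the sources used here, so a count of 0 may not show the level of genes with near-identical copies.

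The order of the first 3 genes was the same in each of the 8 animals. The most abundant gene exceeded the next by 3.45 ± 0.39 on the log2 scale (SD, n = 8), a geometric mean ratio of 10.95, which ranged from 7.45 to 16.7 between animals. The gene at rank 2 exceeded that at rank 3 by 2.05 ± 0.43, and the gene at rank 3 exceeded that at rank 4 by 0.88 ± 0.26. Each of these 3 differences was positive in 8 of 8 animals (two-sided exact sign-flip permutation test over animals, p = 0.0078, Benjamini-Hochberg adjusted p = 0.049 over 19 neighbouring pairs). That p is the smallest 8 animals can give. The genes were ordered by their means over these same animals, which favours a positive difference, and the p-values do not allow for this. None of the other 16 neighbouring pairs among the first 20 genes passed, and their adjusted p-values ranged from 0.48 to 0.95 (same exact test). Rank 4 exceeded rank 5 in 7 of 8 animals by 0.40 ± 0.60, for example, and rank 6 exceeded rank 7 in 5 of 8 by 0.05 ± 0.48. From rank 4 on, neighbours were thus not told apart by this test. When the genes were ranked by their median, 6 pairs passed. With any 1 animal left out no pair passed. The smallest p that 7 animals allow in the sign-flip test, 0.0156, passes the adjustment only where enough of the 19 pairs reach it. The lists of individual animals overlapped accordingly: 5 genes were among the first 10 in every animal and 13 among the first 20, while 15 genes entered the first 10 of at least 1 animal and 31 the first 20.

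The next comparison asked how far the animals differed. For the 80 genes with a mean of at least 100 CPM, the SD of log2(CPM + 1) between animals had a median of 0.41, with quartiles at 0.32 and 0.58. The median coefficient of variation was 27.5%, where counting error alone would give 1.55%. As a check of whether depth limits these values, each gene's reads were reassigned at random to the libraries in proportion to their depth. All 80 genes exceeded counting error at an adjusted p under 0.05, as did 237 of all 402 genes with reads. The p was 1e-04 for each of the 20 most abundant genes, the smallest that 10000 random draws can give. This check sets the spread between libraries against counting noise alone and does not test for differences between animals. The highest animal exceeded the lowest by a median of 2.35 times. It did so by less than 2 times in 24 genes and by at least 4 times in 14. Each animal gave a single library, so the spread between animals includes that of culture and library preparation.

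**Figure D2:**
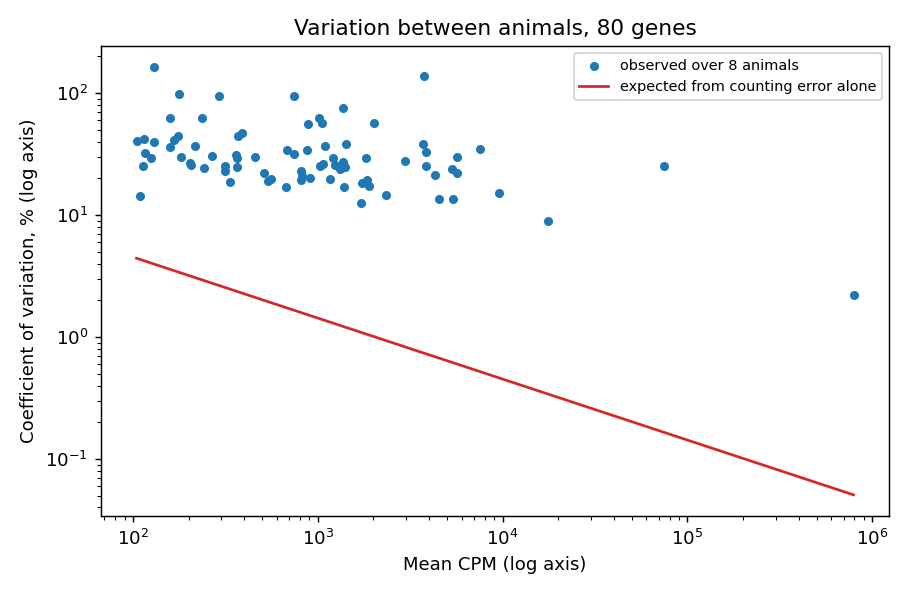
Coefficient of variation over 8 animals (percent, log axis) against mean CPM (log axis) for the 80 genes with a mean of at least 100. Points are genes, and the line is the value expected from counting error alone. Every point lies above the line, whose median is 1.55% against 27.5% for the genes.

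Among the genes with a mean of at least 100 CPM, the 5 with the smallest SD on the log2 scale were those at rank 1 (0.03), rank 3 (0.13), rank 23 (0.19), rank 8 (0.19) and rank 10 (0.20). The value for ENSBTAG00000029897 depends on the scaling, because a gene that holds most of the reads cannot rise far as a share of its library. With median-of-ratios size factors its SD was 0.16 and with TMM factors 0.13. At rank 3 the SD moved less, to 0.18 under both.

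In several of the most variable genes a few animals set much of the spread. ENSBTAG00000048038, at rank 63, had the largest SD of log2 values, 1.95. It averaged 310 ± 68.9 CPM (SD) in 6 animals, with values from 228 to 436, but lay at 14.3 in animal 3 (52 reads) and 17.9 in animal 8 (83 reads). Over all 8 animals its mean was 237 ± 148.1 (SD, n = 8). Its SD of log2 values was still 1.66 without animal 8. ENSBTAG00000029844, at rank 73, was high in animal 8 alone. Its level there was 651 CPM against 30.3 to 76.3 in the other 7 animals, 8.53 times the highest of them, and its SD of 1.33 became 0.44 without animal 8. Likewise, the gene at rank 14 (SD 1.32) peaked in animal 8, at 16287 CPM against 985 to 3763 elsewhere. Without that animal its SD was 0.74. At rank 68 (SD 1.08), the gene had 565 CPM in animal 8 and 61.4 to 292 in the others, and an SD of 0.73 without animal 8. At rank 45 (SD 1.16), the level reached 2333 in animal 8 and 1025 in the next animal, and the SD was 0.86 without animal 8.

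The remaining 3 of the 8 most variable genes split the animals differently. The gene at rank 18 (SD 1.29) lay at 318 CPM in animal 8 and 473 in animal 1, and between 1539 and 3270 in the other 6 animals. That at rank 60 (SD 1.27) lay at 843 in animal 8 and 599 in animal 7, against 67.4 to 263 elsewhere. Levels at rank 71 (SD 1.19) were 35.1 in animal 2 and 38.3 in animal 8. In the others they ranged from 86.9 in animal 1 to 319 in animal 4. These SDs fell less without animal 8, to 0.97 at rank 18, 1.04 at rank 60 and 1.06 at rank 71. In all, 9 of the 80 genes had an SD of at least 1 on the log2 scale. Without animal 8 there were 4.

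**Figure D3:**
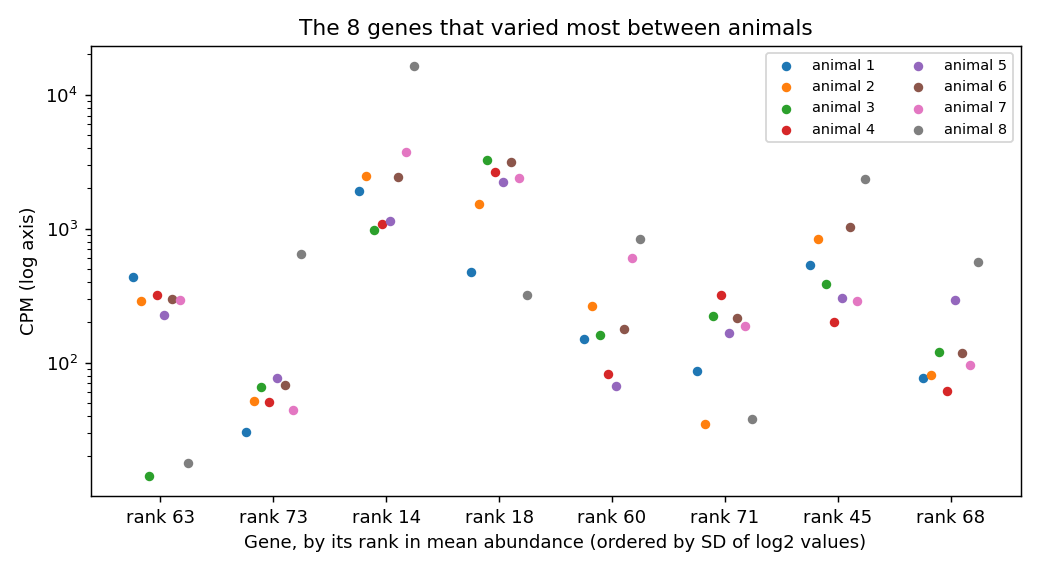
CPM (log axis) of the 8 genes with the largest SD of log2 values among those with a mean of at least 100, labelled by rank in mean abundance. Each point is 1 animal. Animals 3 and 8 lie at 14.3 and 17.9 for the gene at rank 63, and animal 8 is the highest for the genes at ranks 73, 14, 60, 45 and 68.

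Finally, the libraries were compared with one another across the genes with a mean of at least 10 CPM. Pairs among animals 1 to 7 correlated with Pearson's r between 0.959 and 0.984 and Spearman's rho between 0.947 and 0.977. Pairs with animal 8 had r between 0.903 and 0.949 and rho between 0.888 and 0.935, below every pair of the other animals. These correlations run across genes, which are not independent replicates. Of the 80 more abundant genes, animal 4 was the highest in 23, more than any other animal, and animal 8 in 17. Animal 8 was the lowest in 26, followed by animals 1 and 5 with 14 each. An even share would be 10 in each direction. These counts were taken on the deposited scaling, were not rerun under another, and can change with it. Median-of-ratios factors were 1.13 in animal 4 and 1.23 in animal 6, against 0.92 in animal 1. By more than 1.5 times animal 8 exceeded the highest of the others in 7 genes and fell short of the lowest in 4. Of the 7, the gene at rank 73 reached a mean of 100 CPM only through animal 8. Among the other animals, animal 5 fell short of the lowest by that margin in 4 genes, animals 1 and 7 in 2 each, and animal 1 exceeded the highest in 1. No other animal did either in any of the 80 genes. The library of animal 8 held 4626747 reads, within the range of the others. As a check for a library deposited more than once, each pair was set against counting error. The smallest variance between 2 libraries was 105 times the counting variance, so all 8 were kept as separate samples.

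**Figure D4:**
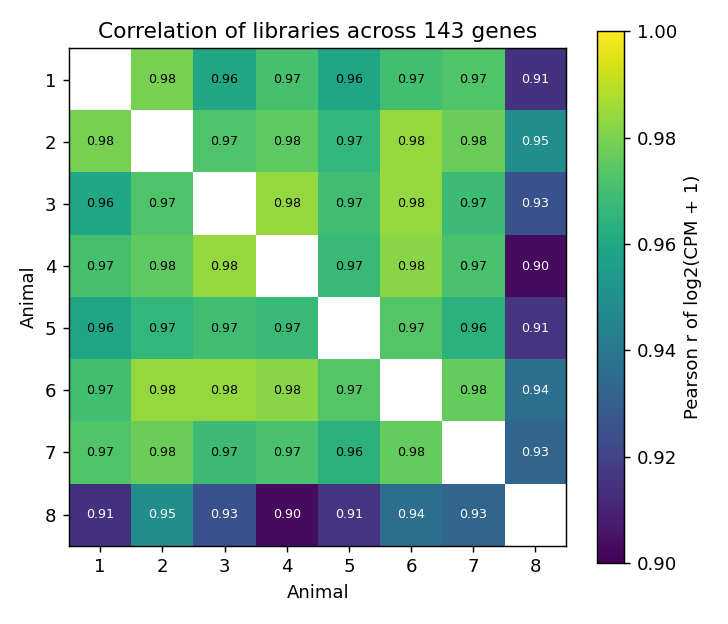
Pearson correlation of log2(CPM + 1) across the genes with a mean of at least 10 CPM for each pair of the 8 animals, on a colour scale from 0.9 to 1. The row and column of animal 8 hold the lowest values, from 0.903 to 0.949, and all other pairs lie at 0.959 or above.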

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

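The Dixon ratio of the median correlations was fixed before the data were examined. All tests of explanations in this part were chosen after the data had been seen. Dixon's test at the 95% level was applied to 27 described genes and 8 measures of the libraries. Chance alone marks about 1 in 20 groups, but not for the 8 genes chosen for their large SD, of which 4 were marked. Of the other 19 genes 1 was, about the chance rate.

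Animal 8 stood apart from the other 7 in 3 measures of the libraries. Its median Pearson correlation with the others was 0.925, against 0.966 to 0.976 for the rest, and its median Spearman correlation was 0.914, against 0.957 to 0.969. These are forms of the same measure and not independent of each other. Every library was also thinned to 3638161 reads in a single random draw. Animal 8 then had reads for 316 genes, against 273 to 293, a Dixon ratio of 0.535 that barely passed. With all reads it had 326, against 283 to 304, a ratio of 0.512 that did not pass. The 4 marked genes with a large SD also had their high value in animal 8, with 16287 CPM at rank 14, 2333 at rank 45, 565 at rank 68 and 651 at rank 73. That value is part of why they were chosen, so they are no separate evidence on this animal. Of the 80 genes with a mean of at least 100, 10 held an outlying animal, where chance gives 4, and in 7 of the 10 it was animal 8 on the high side. On the log2 scale 5 genes did, and animal 8 in 1 of them, the gene at rank 73, so this count and the calls at ranks 14, 45 and 68 rest on the linear scale. The gene at rank 73 reached a mean of 100 only through animal 8, since the other 7 animals lay at 30.3 to 76.3 CPM. Its call is therefore no separate evidence on this animal on either scale.

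A difference in depth does not account for the distance of animal 8, since the Dixon ratio of its median correlation was 0.799 with all reads and 0.788 after thinning, above the critical value for 8 samples both times. The 2 most abundant genes together took 86.3% of the reads in animal 8, within the 84.9 to 88.3% of the other 7. That sum cannot exclude unusual shares in a few genes, because opposite deviations cancel in it. Animal 8 had the highest share of the first gene (81.4%) and the lowest of the second (4.89%). Without these 2 genes the Dixon ratio of the lowest median correlation was 0.792, so they do not account for the distance by themselves. Cells of another type in the preparation remain open: 7 genes exceeded every other animal by over 1.5 times, but without microRNA names their cell type could not be read. The culture step removed non-adherent cells. The labels give no trait that sets this animal apart, so no biological explanation was tested.

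ENSBTAG00000048038 was low in animals 3 and 8 and was described among the most variable genes. Its split left a gap of 3.60 on the log2 scale between the 2 animals and the other 6, and it was the only one of the 80 genes with a gap of at least 2 that left 2 or more animals on each side. A difference in depth does not account for it: at the level of the lowest of the other 6 animals, 829.2 reads would be expected in animal 3 (95% counting interval 773 to 886) and 52 were found. In animal 8 there were 83 against 1054.5 expected. Reads counted on another gene of the table in those animals were searched for, and 0 genes rose in both by the missing 294 CPM, but 51 genes vary enough between the other animals to hide that amount, so this stays open. A candidate explanation is a sequence variant carried by those animals that lowers expression or prevents the reads from matching the reference; the reads themselves would be needed to tell, and they were not used here.

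The gene at rank 6 had 8537 CPM in animal 4, against 4803 to 6455 in the others. Its Dixon ratio was 0.558 on the linear scale, and on the log2 scale it was 0.486, which no longer passed. The ratio was not computed under other scalings. Median-of-ratios factors would lower the value of animal 4 (factor 1.13) and raise that of animal 1 (0.92), the next highest.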

How the results depend on the processing

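The share of the most abundant gene, that of the first 10, the number of genes holding 90% of the reads (5), the median SD between animals and the number of genes varying beyond counting error kept within their spread or within 1.5 times under every alternative run for them. Leaving out each animal in turn gave a share of 78.9 to 79.7% for the most abundant gene, 92.64 to 92.96% for the first 10, 5 to 6 genes holding 90% of the reads, a median SD of 0.36 to 0.43 and 79 to 80 genes beyond counting error. The count beyond counting error says little about stability, because all 80 genes passed in the main setting with spreads far above counting error. The number of detected genes with a mean of at least 10 followed the minimum by construction, and became 402 with any read and 80 with a mean of at least 100. The 9 genes with an SD of at least 1 became 21 with any read and 3 with a minimum mean of 1000, and 4 to 9 when single animals were left out, the lowest without animal 8. Neighbouring ranks told apart numbered 3 when ranked by the mean and 6 when ranked by the median, the cause of which was not tested. They numbered 0 with any 1 animal left out, where too few pairs reached the smallest p that 7 animals allow. The Dixon ratio of the lowest median correlation was 0.799, and from 0.266 to 0.839 with single animals left out, the lowest without animal 8, where no other animal then stood apart. Animal 8 stayed past the critical value with Spearman's rho, other pseudocounts, other minimum levels and thinning. Median-of-ratios factors differed from the deposited scaling by -0.12 to 0.29 on the log2 scale, most in animal 6. Of 156 alternative values for the SD of single described genes, 8 moved by more than their standard error: 3 without animal 8 (the genes at ranks 14, 68 and 73), and 5 in the genes at ranks 1 and 3 under other scalings or, for rank 1, without animal 4 (0.022 against 0.032). Comparisons that need microRNA names, and their other settings, were not run. No paired analysis was possible because there is a single group. Rank comparisons, the test against counting error, thinning, TMM, the scaling without the leading genes and all alternatives for the similarity of libraries were chosen after seeing the data. Depth limits the genes under 10 CPM, where 3 reads amount to 0.509 to 0.825 CPM.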

Other observations

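Some moderately abundant genes lay more than 1.5 times beyond the range of the others in an animal other than animal 8. Of those given here, Dixon's test marked the gene at rank 37 on both scales (ratio 0.797 linear, 0.658 log2), and those at rank 69 (0.354 and 0.601) and rank 42 (0.439 and 0.546) on the log2 scale alone. These genes were picked for their distance from the other animals, so the marks are no separate evidence. Over all 80 genes 5 were marked on the log2 scale, where chance gives 4. In animal 5, the gene at rank 69 lay at 36.1 CPM against 130 to 301 in the other 7 animals, and that at rank 52 at 104 against 263 to 633. The genes at ranks 15 and 74 were also lowest there, at 1255 against 1925 to 5098 and 57.1 against 93.4 to 234. In animal 1, the gene at rank 37 reached 2555 against 649 to 1036, while those at ranks 28 and 66 were lowest, at 408 and 97.3. In animal 7, the genes at ranks 42 and 56 were lowest, at 446 and 162. Of the 63 genes with reads in a single animal, 23 had them in animal 8. The first principal component of the genes with a mean of at least 10 CPM held 40.9% of the variance between animals, and animal 8 carried 77.8% of its squared weight. The second held 21.5%, with its largest squared weight, 39.2%, in animal 1. The third held 13.8%, with 80% in animal 5.

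Genes also varied together between animals. This was seen in the data first, and all tests of it were chosen afterwards. Among the 3160 pairs of the 80 genes with a mean of at least 100, 7.18% had an absolute Pearson r above 0.8 over the 8 animals, against 1.04 to 2.66% in 1000 sets in which each gene's values were shuffled on their own, so independent variation of single genes does not account for it. The library of animal 8 alone does not either, since the share over the other 7 animals was 7.18%, against at most 4.43% in shuffled sets. The excess was smaller without animal 8, because the median of the shuffled sets was 3.16%, against 1.79% with all 8 animals. Scaling to 1000000 reads in libraries led by 1 gene is argued against by a share of 7.36% when CPM were computed without the 2 most abundant genes, against at most 2.83%. Leaving out any other animal gave 7.97 to 11.96%, against at most 4.81% in shuffled sets of 7 animals. Shuffled sets also gave more with 7 animals, so these shares cannot be set directly against those over 8. Median-of-ratios factors over all 8 animals gave 6.27%, against at most 2.53%. Shared transcription of neighbouring microRNA genes may contribute, as may differences in cell state or cell composition between animals. Neither was tested, because the genes could not be named or placed. With 1 library per animal, effects of culture or library preparation on many genes cannot be told apart from differences between animals.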
